A study of Homo sapiens with 9 samples.

How the data were processed

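The series measured messenger RNA on Illumina BeadChip arrays in 9 samples of 1 cell line, LNCaP-abl, in 3 groups of 3 set by the siRNA named in the labels. Per the labels' protocols, cells received 25 nM of siRNA against Wnt5A, of siRNA against SRC1 or of a non-targeting siRNA (siNT). RNA was taken 72 h later and copied into biotin-labelled RNA from an oligo(dT) primer. The siNT arrays carry the replicate numbers 2, 3 and 4, and those of each knockdown 1, 2 and 3.

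A deposited table gives, for 47323 probes, the intensity of each probe on each array before normalization, with its detection p-value, per the file headers. The deposited intensity values are linear, and none is negative. Whether a background had been subtracted by the scanner software is not given in the sources used here. The detection p-value moves in steps of 1 in 770. A second table, the authors' value table, holds the authors' processed values for 23043 of these probes on a log2-like scale. It was made with lumi, per the submitters' processing notes, and the version, the transform and the normalization are not given in the sources used here. Each of its 9 columns correlated best with its own array (0.9973 to 0.9987), so their direction is settled. All 9 columns have a median of 8.018, and weak signals are compressed in them. It holds every probe with a detection p under 0.01 on at least 1 array and 3342 that never reached it, and the rule by which probes were kept was not established.

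The non-normalized intensities were background-corrected with limma's normexp method. Its background parameters were inferred from the detection p-values, and an offset of 16 was added. The values were then taken to log2 and quantile normalized (limma 3.58.1, R 4.3.3). Probes with a detection p under 0.01 on at least 3 of the 9 arrays were kept, which left 17088. Symbols came from a platform annotation table that lists 16978 probes, of which 16973 have 1 symbol and 5 several. Of the symbols, 16958 were matched by gene identifier to a current gene table and 0 needed an update. Of the probes kept, 13472 had 1 symbol and 3616 did not and were not named. A gene was represented by its probe with the highest mean, which gave 10361 genes, 2576 of them with more than 1 probe kept. A second probe of a called gene was called in the opposite direction for 1 gene in siWnt5A, 2 in siSRC1 and 5 between the knockdowns.

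Groups were compared in 1 linear model over all 9 arrays with limma (lmFit, contrasts and moderated statistics) with 10 degrees of freedom after moderation. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Positive log2 fold changes are higher in the first group named. SE is the moderated standard error, and levels are means ± SD over 3 arrays. Where a probe was not detected (detection p under 0.01) on any array of 1 group, its fold is given as a bound ("at least"): the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's value and the lowest value among detected probes. The array number limits the precision: the median SE of a log2 fold change was 0.118.

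Gene lists were written before the data were examined: 27 lists with 726 genes, of which 499 were measured. The 24 lists with at least 5 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. limma's fry was also run. It asks whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes. For each list the count of genes is also given adjusted over the list alone.

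The genes named were set by a rule before the data were examined. It took WNT5A and NCOA1; for each knockdown against siNT the 6 called genes with the largest positive and the 6 with the largest negative log2 fold change; and up to 3 called genes per direction with the smallest adjusted p from at most 8 lists. For siWnt5A against siSRC1 it took the 5 largest differences per direction. Of the genes called in both knockdowns, it took 5 per direction with the same sign and 3 per pattern with opposite signs. Uncharacterised loci were left out of the ranks by fold change, which used fitted values, so a gene given as a bound has no secure rank. Genes from outside this rule are named as such.

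Both knockdowns share the siNT arrays. Unchanged groups were therefore simulated 100 times from the deviations of the arrays within their groups, and the values are given beside the observed ones. The steps were tested on simulated data for the comparison of siWnt5A with siNT, with 200 changed genes among 10361 over 20 runs. Of the changed genes, 57.1% were called at 1.5-fold, 88.1% at 2-fold, 97.3% at 3-fold and 99.2% at 4-fold, and 5.71% of calls were false. That share may not hold where arrays deviate together. In 1 of the 100 simulated sets of unchanged groups, drawn from the deviations of the arrays, 1406 genes were called in a comparison. Alternatives covered the offset, the background correction, median scaling, the authors' value table, the filter on dim probes, the choice of probe, the moderation, array weights, fits of only the groups compared, the replicate number as a block and leaving out each array. The files name no slides or positions, so no slide effect was fitted. Probe sequences and genome positions were not used here. Of the genes that rose most in siSRC1, 1 is not reported here, for a reason unrelated to its values.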

Results

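LNCaP-abl (Abl) is a human prostate cancer line obtained from LNCaP by long culture without androgen, and it is used as a model of castration-resistant growth. The cells were kept in charcoal-stripped serum, which is poor in steroids, and were transfected with 25 nM of siRNA against WNT5A, of siRNA against SRC1 or of a non-targeting siRNA (siNT). WNT5A is a secreted Wnt ligand best known for signalling that does not run through beta-catenin. SRC1, the product of NCOA1, is a coactivator of steroid receptors. The question was which transcripts depend on each of them 72 h after transfection. There were 3 arrays per group and 9 in all, and each knockdown used 1 siRNA. Effects of an siRNA on transcripts other than its target were not tested, so a change cannot be assigned to loss of the target alone. Between 15584 and 16987 of the 47323 probes were detected per array (32.9% to 35.9%), and the median intensity lay between 127.8 and 133.4. Across the 10361 genes tested, arrays of 1 group correlated at 0.9882 to 0.9929 and arrays of different groups at 0.9723 to 0.9869. No pair of arrays held identical intensities. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

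WNT5A was lower in the siWnt5A arrays. Its normalized intensity was 1690 ± 110 in siNT and 611 ± 55.2 in siWnt5A (SD, n = 3 each), which leaves 36.1% of the siNT level (log2 fold change -1.47, SE 0.10, limma adjusted p = 4.69e-05). The single values were 1816, 1641 and 1612 in siNT replicates 2, 3 and 4, and 547.2, 643.8 and 641.9 in siWnt5A replicates 1, 2 and 3. NCOA1 was lower in the siSRC1 arrays, at 70.4 ± 7.01 against 288.3 ± 13.5 in siNT (24.4% of siNT; log2 fold change -2.04, SE 0.10, adjusted p = 1.22e-05). Without background correction that fold change was -1.09, and -0.965 in the authors' value table, so the level left depends on the correction. Its values were 290.8, 273.7 and 300.3 in siNT replicates 2, 3 and 4, 292.4, 255.8 and 251.2 in siWnt5A replicates 1, 2 and 3, and 63.6, 77.6 and 70.0 in siSRC1 replicates 1, 2 and 3. The other 2 NCOA1 probes were not detected on any siSRC1 array. The dimmer of them was also not detected on any siWnt5A array or on siNT replicate 3. Both targets thus moved as the labels state. NCOA1 in siWnt5A was 266.5 ± 22.6 (log2 fold change -0.12, adjusted p = 0.502). WNT5A also fell in siSRC1, to 1207 ± 75.4, with single values of 1292, 1148 and 1181 (71.4% of siNT; log2 fold change -0.49, SE 0.10, adjusted p = 0.0136). That call was lost without siNT replicate 2 (adjusted p = 0.0579), without siSRC1 replicate 2 (0.0547) and in the fit with the replicate number as a block (0.0987), the highest value over 21 settings.

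**Figure D1:**
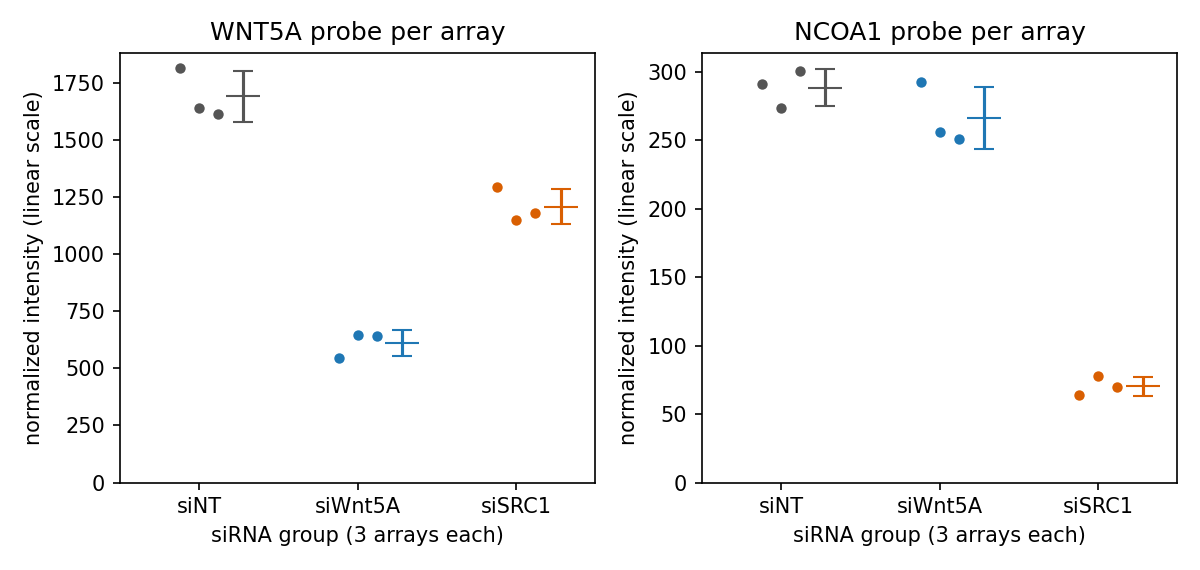
Normalized intensity (linear scale) of the WNT5A probe (left) and of the brightest NCOA1 probe (right) on each of the 9 arrays, by siRNA group; points are arrays, and the bar beside them is the mean ± SD of 3 arrays. WNT5A lies at 611 ± 55.2 in siWnt5A against 1690 ± 110 in siNT, and NCOA1 at 70.4 ± 7.01 in siSRC1 against 288.3 ± 13.5 in siNT.

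After WNT5A knockdown, genes of cell division were lower than with siNT, and so were 9 of 18 NF-kB targets and inflammatory cytokines. Lower, too, were 6 of 13 steroid-metabolizing genes, a list that did not pass by camera with an estimated correlation (adjusted p = 0.332). Of 34 measured M-phase genes 28 fell and none rose, among them the mitotic kinase AURKA (log2 fold change -1.07, SE 0.08), the spindle-associated HMMR (-1.09, SE 0.11) and NUF2 of the kinetochore (-0.73, SE 0.08). The chemokines CCL2 (-1.78, SE 0.16) and CXCL10 (-0.95, SE 0.09) fell, as did the mitochondrial superoxide dismutase SOD2 (-1.12, SE 0.10). The aldo-keto reductases AKR1C2 (-2.03, SE 0.17) and AKR1C3 (-0.93, SE 0.16), which interconvert active and inactive steroids, were lower as well. In all, 1078 of 10361 genes were called, 377 higher and 701 lower, of which 2 were higher and 53 lower by at least 2-fold, with bounds in place of folds for undetected probes.

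The largest falls were in CYP24A1, the enzyme that inactivates vitamin D (log2 fold change -2.10, SE 0.15), AKR1C2, CKS1B, a subunit of cyclin-dependent kinases (-1.94, SE 0.09), AKR1C4, a liver-type member of the same reductase family (-1.93, SE 0.20), TPGS2, a tubulin-modifying enzyme subunit (-1.93, SE 0.11), and the protease inhibitor SERPINB7 (-1.88, SE 0.09). Adjusted p ranged from 5.41e-06 (CKS1B) to 6e-04 (AKR1C4). The AKR1C genes are near-identical in sequence, so their probes may share signal. Rises were smaller. Among the largest were the small nuclear RNA RNU4-1 (1.04, SE 0.18), the arylamine acetyltransferase NAT2 (1.03, SE 0.15), the phosphatase subunit PPP6R2 (0.96, SE 0.25; call lost in 9 alternative settings), the zinc-finger gene ZNF557 (0.93, SE 0.24; lost in 7) and the small nucleolar RNA SNORD3A (0.91, SE 0.22; lost in 6), with adjusted p from 0.00291 (NAT2) to 0.0398 (ZNF557). UNC5A, a netrin receptor that was not detected on any siNT array, was at least 1.70-fold higher (adjusted p = 0.000296). RNU4-1 and SNORD3A do not carry the poly(A) tail of most messenger RNAs, from which the labelling starts.

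By list, the M-phase genes had a median log2 fold change of -0.73 (camera adjusted p = 9.61e-24; adjusted p = 0.0401 with an estimated correlation), and 33 of 34 fell when adjusted over the list alone. NF-kB targets and inflammatory cytokines had a median of -0.52 (adjusted p = 1.52e-08; adjusted p = 0.0143 with an estimated correlation). Of the 18 measured, 9 fell and none rose, and 11 fell when adjusted over the list alone. Of 30 DNA replication genes 10 fell, including CDC45 of the replicative helicase (-1.39, SE 0.18), the clamp-loader subunit RFC5 (-0.95, SE 0.12) and the polymerase subunit POLE2 (-0.80, SE 0.11), and 15 fell when adjusted over the list alone. The list's median was -0.31 (adjusted p = 7.19e-06), but adjusted p = 0.332 with an estimated correlation. Of 13 steroid-metabolizing genes 6 fell (9 adjusted over the list alone), with a median of -0.48 (adjusted p = 2.67e-05; adjusted p = 0.332 with an estimated correlation). UGT2B28, which glucuronidates steroids and was not detected on any siWnt5A array, was at least 1.21-fold lower, and its close relatives may share its signal. Of 10 luminal prostate markers 5 fell, also when adjusted over the list alone, among them the secreted MSMB (-0.76, SE 0.12), the surface glycoprotein CD24 (-0.50, SE 0.10) and the protease TMPRSS2 (-0.39, SE 0.08; call lost in 5 alternative settings). Their median was -0.23 (adjusted p = 0.00987; adjusted p = 0.332 with an estimated correlation).

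Among the lists that did not pass, 5 of 11 TGF-beta and BMP targets fell and none rose, also when adjusted over the list alone. They included the helix-loop-helix inhibitors ID1 (-1.04, SE 0.11) and ID3 (-0.46, SE 0.10) and the receptor BMPR2 (-1.42, SE 0.16). The list's median (0.04) and mean (-0.25) differed in sign (adjusted p = 0.173). Of 23 androgen-regulated genes 2 rose, TPD52, a vesicle-trafficking protein (0.41, SE 0.10; call lost in 5), and the elongation factor partner EAF2 (0.35, SE 0.10), whose call was lost in 18 alternative settings. FOLH1, the prostate-specific membrane antigen (-0.61, SE 0.10), CENPN of the centromere (-0.49, SE 0.10) and TMPRSS2 were among the 4 that fell. Adjusted over the list alone, 2 rose and 5 fell, and the list as a whole did not pass by camera (median -0.05, adjusted p = 0.396). Of 14 beta-catenin targets 1 fell, MYC (-0.70, adjusted p = 0.00508; named after its value was seen), also when adjusted over the list alone (median -0.05, adjusted p = 0.553). Of 31 Wnt5A receptors and non-canonical Wnt components 2 rose and 2 fell, WNT5A included, and 2 rose and 4 fell when adjusted over the list alone (median 0.00, adjusted p = 0.396). Markers of other cell types were few. Of 4 measured fibroblast and smooth muscle markers ACTA2 fell (-0.45, SE 0.10; call lost in 6 alternative settings), and FBLN1 was at least 1.11-fold lower, a call lost in 9 alternative settings. Of 4 blood and endothelial markers 1 fell, 2 of 10 neuroendocrine markers fell (median -0.13), and the counts were the same adjusted over the list alone except for 1 neuroendocrine marker that then rose. Neither of 2 basal markers was called by limma or had an unadjusted p under 0.05.

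The number of genes called was 491 without siNT replicate 2, 441 without siNT replicate 3 and 594 without siWnt5A replicate 1 and without siWnt5A replicate 2. Without background correction fold changes shrink by construction, and the M-phase median was then -0.38, and -0.33 in the authors' value table.

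After SRC1 knockdown, genes of cell division were again lower than with siNT, and so were genes of the ATF4 and unfolded protein response. Of the 34 M-phase genes 30 fell and none rose, among them CDC20, the activator of the anaphase-promoting complex (log2 fold change -1.55, SE 0.10), the mitotic kinesin KIF20A (-1.35, SE 0.09) and NUF2 (-1.09, SE 0.08). Of 32 ATF4 and unfolded protein response genes 14 fell and none rose, including the amino acid transporter SLC7A5 (-0.73, SE 0.09), the transcription factor CEBPB (-0.64, SE 0.08) and EDEM1, which clears misfolded glycoproteins (-0.71, SE 0.08). Some interferon-stimulated genes were higher, such as IFIT3 (0.65, SE 0.12) and IFI44 (0.61, SE 0.13). The call of IFIT3 was lost with the mean of its probes (limma adjusted p = 0.164), and that of IFI44 in 3 alternative settings. In all, 1055 of 10361 genes were called, 489 higher and 566 lower, of which 15 were higher and 69 lower by at least 2-fold, counted in the same way.

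The largest falls were in PLAT, tissue plasminogen activator (log2 fold change -2.15, SE 0.20), NCOA1 itself, COPG2, a coat protein of Golgi vesicles (-2.03, SE 0.13), the lysosomal protease CTSV (-2.01, SE 0.08) and CDC20. MND1, a meiotic recombination factor that was not detected on any siSRC1 array, was at least 2.31-fold lower. Adjusted p ranged from 2.19e-06 (CTSV) to 0.000714 (MND1). Among the largest rises were the tight junction protein CLDN8 (1.71, SE 0.22), the tetraspanin TSPAN8 (1.30, SE 0.15) and the LIM-domain gene LMCD1 (1.29, SE 0.10). EPSTI1, an interferon-inducible gene, and CFAP95, a protein of cilia, were not detected on any siNT array and were at least 2.93-fold and at least 1.47-fold higher. Adjusted p for these 5 genes ranged from 0.0001 (LMCD1) to 0.00153 (CLDN8).

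By list, the M-phase genes had a median log2 fold change of -1.05 (camera adjusted p = 6.84e-33; adjusted p = 0.035 with an estimated correlation), and 33 fell when adjusted over the list alone. The ATF4 and unfolded protein response genes had a median of -0.39 (adjusted p = 5.26e-13; adjusted p = 0.0393 with an estimated correlation), and 18 fell when adjusted over the list alone. Of 30 DNA replication genes 12 fell (14 adjusted over the list alone), among them CDC45 (-1.47, SE 0.18), the flap nuclease FEN1 (-1.14, SE 0.12) and TYMS, which makes thymidylate (-1.04, SE 0.13). The list's median was -0.36 (adjusted p = 1.03e-09; adjusted p = 0.0959 with an estimated correlation). Of 18 NF-kB targets and inflammatory cytokines 4 fell, also when adjusted over the list alone, with a median of -0.20 (adjusted p = 3.22e-04; adjusted p = 0.0393 with an estimated correlation). They included the cytokine TNF (-1.05, SE 0.15), SOD2 (-0.99, SE 0.10) and RELB, an NF-kB subunit (-0.94, SE 0.16). Of 20 cholesterol synthesis genes 3 rose (4 adjusted over the list alone), with a median of 0.14 (adjusted p = 0.0369; adjusted p = 0.442 with an estimated correlation). That list passed in 14 of 22 alternative settings, with an adjusted p of up to 0.158 without siNT replicate 3.

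Of 27 interferon-stimulated genes 5 rose and 2 fell, and 8 rose and 3 fell when adjusted over the list alone (median 0.11, adjusted p = 0.214). Beside IFIT3 and IFI44, the ubiquitin ligase HERC5 rose (0.33, SE 0.08; call lost in 8 alternative settings), while the transcription factor IRF7 (-0.43, SE 0.09; call lost in 5) and the oligoadenylate synthetase OAS3 (-0.56, SE 0.15; call lost in 13) fell. Of 11 TGF-beta and BMP targets ID1 rose (0.95, SE 0.11), and LTBP3, which anchors latent TGF-beta (-0.43, SE 0.08), and the repressor TGIF1 (-0.44, SE 0.10; call lost in 6) fell. Adjusted over the list alone 4 rose and 2 fell (median 0.14, adjusted p = 0.563). Of 9 YAP and TEAD targets the matricellular protein CCN1 rose (1.18, SE 0.24) and the phosphatase PTPN14 fell (-0.76, SE 0.17; call lost in 6), also when adjusted over the list alone (adjusted p = 0.717). Of 23 androgen-regulated genes 2 rose and 1 fell, also when adjusted over the list alone (median -0.04, mean 0.06, adjusted p = 0.772). None of 14 beta-catenin targets was called by limma (6 at an unadjusted p under 0.05; adjusted p = 0.781), and 2 rose and 3 fell when adjusted over the list alone. Of 31 Wnt5A receptors and non-canonical Wnt components 1 rose and 3 fell, WNT5A among them, with the same counts adjusted over the list alone (adjusted p = 0.71). Of 4 blood and endothelial markers the clotting factor VWF, not detected on any siNT array, was at least 1.67-fold higher, and the lysosomal CD68 fell (-0.55, SE 0.11). None of 4 fibroblast or 2 basal markers was called by limma (3 and 0 at an unadjusted p under 0.05), and 1 of 10 neuroendocrine markers rose (median 0.14). Adjusted over the list alone, 2 fibroblast and 3 neuroendocrine markers rose and 1 and 2 fell.

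The number of genes called was 612 without siNT replicate 2, 654 without siNT replicate 3, 696 without siSRC1 replicate 1 and 604 without siSRC1 replicate 2. Of the ATF4 and unfolded protein response genes 9 fell without siSRC1 replicate 2, and the M-phase median was -0.50 without background correction and -0.44 in the authors' value table.

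**Figure D2:**
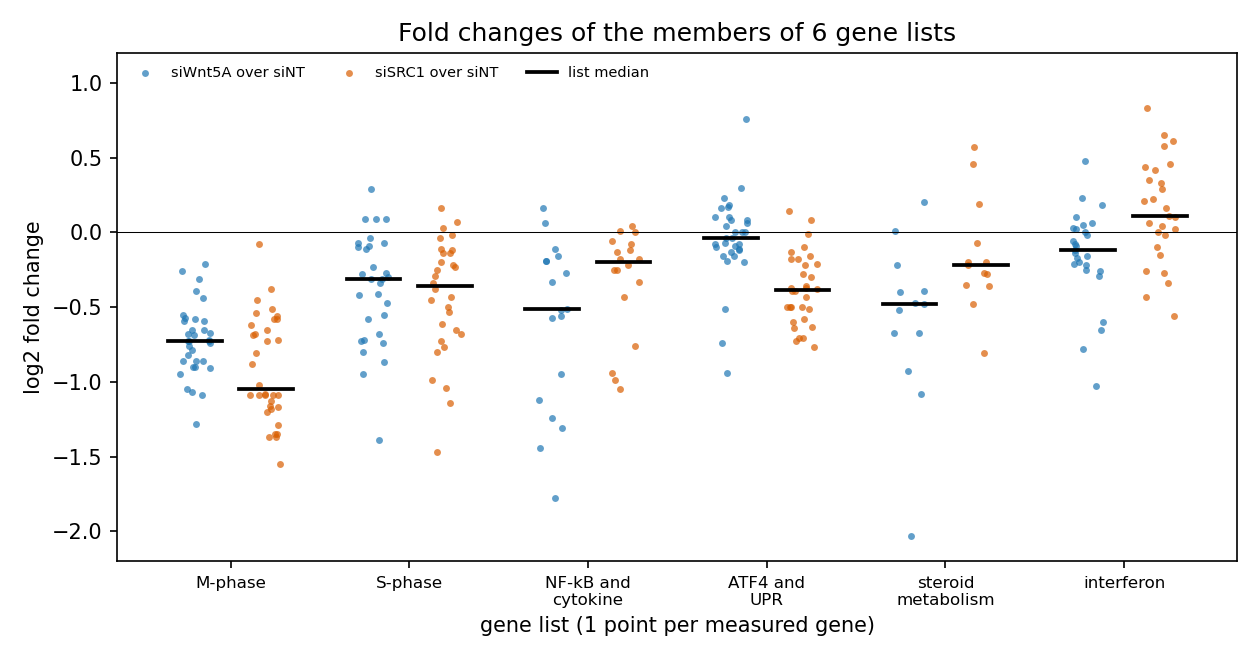
Log2 fold change against siNT of each measured gene (1 point per gene, y axis) in 6 gene lists (x axis), for siWnt5A (blue) and siSRC1 (orange); black lines are list medians. The M-phase medians lie at -0.73 and -1.05, and the ATF4 and unfolded protein response (UPR) medians at -0.04 and -0.39.

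Some lists passed in 1 knockdown and not in the other. In siWnt5A, 3 of 32 ATF4 and unfolded protein response genes fell and 1 rose (median -0.04, adjusted p = 0.553), with the same counts adjusted over the list alone, and 0 of 20 cholesterol synthesis genes were called by limma (median 0.05, adjusted p = 0.396; 6 at an unadjusted p under 0.05). In siSRC1, 1 of 13 steroid-metabolizing genes rose and 1 fell (median -0.22), and 1 of 10 luminal markers fell (median -0.13), with the same counts adjusted over the list alone and adjusted p = 0.214 for each. Interferon-stimulated genes in siWnt5A (1 rose, 2 fell; median -0.12, adjusted p = 0.18) and YAP and TEAD targets (1 fell; median 0.07, adjusted p = 0.992) did not pass, with the same counts adjusted over the list alone. Of the other lists tested, none passed by camera in either knockdown, while fry, which does not compare a list with other genes, called fatty acid genes (adjusted p = 0.015) and epithelial-mesenchymal and adhesion genes (adjusted p = 0.0346) in siWnt5A and immediate-early and ERK feedback genes (adjusted p = 0.0426) in siSRC1. For nuclear receptors and coregulators the medians were -0.06 in siWnt5A and -0.02 in siSRC1, with 1 of 15 genes fallen in siWnt5A, and 1 risen and 1 fallen, NCOA1, in siSRC1. Fatty acid genes (24 measured; -0.09 and -0.03), p53 targets (23; 0.01 and 0.08), epithelial-mesenchymal and adhesion genes (20; -0.15 and 0.00) and hypoxia and glycolysis genes (26; -0.11 and 0.12) held at most 2 called genes per direction. The same was true of cytosolic ribosomal proteins (32; 0.04 and -0.01) and RNA interference machinery (13; 0.17 and 0.10). Respiratory chain genes (30; -0.02 and 0.04), immediate-early and ERK feedback genes (19; 0.18 and 0.00) and apoptosis regulators (25; 0.04 and -0.01) held at most 4. Adjusted over the list alone, these lists held at most 3 per direction, except for 5 immediate-early genes that fell in siSRC1 and 6 apoptosis regulators that fell in siWnt5A. The lowest camera adjusted p in these lists was 0.214 (immediate-early genes, siSRC1).

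The knockdowns were also compared directly. NCOA1 was 3.79-fold higher in siWnt5A than in siSRC1 (log2 fold change 1.92, SE 0.10), and COPG2 (1.70, SE 0.13) and CLGN, a chaperone of the endoplasmic reticulum (1.57, SE 0.09), were higher as well. REEP3, which shapes the endoplasmic reticulum, and UNC5A were not detected on any siSRC1 array and were at least 1.74-fold and at least 1.75-fold higher in siWnt5A. TPGS2 (-2.37, SE 0.11), CLDN8 (-2.32, SE 0.22), ID1 (-1.99, SE 0.11) and SERPINB7 (-1.84, SE 0.09) were lower in siWnt5A, and TSPAN8, not detected there, was at least 2.52-fold lower. Adjusted p ranged from 6.69e-06 (TPGS2 and SERPINB7) to 0.000279 (REEP3). In all, 1820 genes differed by limma, 717 higher and 1103 lower in siWnt5A.

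By list, 16 of 32 ATF4 and unfolded protein response genes were higher in siWnt5A and 1 lower, and 18 and 1 when adjusted over the list alone (median 0.39, adjusted p = 8.29e-08; adjusted p = 0.353 with an estimated correlation). Of 34 M-phase genes 8 were higher in siWnt5A and none lower, also when adjusted over the list alone (median 0.14, adjusted p = 0.00729; adjusted p = 0.516 with an estimated correlation). Of 27 interferon-stimulated genes 11 were lower in siWnt5A and 1 higher, and 14 and 2 when adjusted over the list alone (median -0.37, adjusted p = 0.00856; adjusted p = 0.588 with an estimated correlation). Of 13 steroid-metabolizing genes 4 were lower in siWnt5A and none higher, and 5 when adjusted over the list alone (median -0.29, adjusted p = 0.00856; adjusted p = 0.516 with an estimated correlation). The other lists did not pass by camera. Of 18 NF-kB targets and inflammatory cytokines 7 were lower in siWnt5A and 1 higher, RELB (0.83), and 7 and 2 when adjusted over the list alone (median -0.18, adjusted p = 0.051; adjusted p = 0.414 with an estimated correlation). Of 26 hypoxia and glycolysis genes 1 was lower (median -0.24, adjusted p = 0.051), and of 10 neuroendocrine markers 5 were lower (adjusted p = 0.0802), each also when adjusted over the list alone. Under alternatives these lists passed in 8 (NF-kB), 12 (hypoxia) and 2 (neuroendocrine) of 22 settings. For the rest camera adjusted p in the main fit was at least 0.0956. The number of genes that differed was 1099 without siSRC1 replicate 1 and 1205 without siSRC1 replicate 2.

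Genes called in both knockdowns mostly moved the same way. PLAT fell in both (log2 fold change -1.86 in siWnt5A and -2.15 in siSRC1), and so did SBSN, a protein of keratinizing epithelium (-1.57 and -1.42), CDC45 (-1.39 and -1.47) and CYP24A1 (-2.10 and -1.25). The kinetochore gene SPC25, not detected in either knockdown, was at least 1.65-fold and at least 1.78-fold lower. NAT2 (1.03 and 1.13), the homeodomain protein HOPX (0.80 and 1.26) and the Rab GTPase RAB36 (0.69 and 0.68) rose in both. CROT, a peroxisomal carnitine acyltransferase, was at least 1.32-fold and at least 1.58-fold higher, and BEGAIN, a synaptic protein, at least 1.47-fold and at least 1.27-fold. The call of BEGAIN was lost in 14 of the alternative settings in siSRC1 and in 4 in siWnt5A. In all, 183 genes fell in both and 84 rose in both, against 38.3 and 17.8 for independent lists, and 32 moved in opposite directions.

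Of those 32, 24 fell in siWnt5A and rose in siSRC1, among them TENT5C, a poly(A) polymerase (-0.82 and 0.84), ID1 (-1.04 and 0.95) and the potassium channel subunit KCNS3 (-0.64 and 0.68). The other 8 rose in siWnt5A and fell in siSRC1, including the Golgi proteins TGOLN2 (0.51 and -0.88) and YIPF5 (0.81 and -0.67) and IRF7 (0.48 and -0.43). Of these calls TGOLN2 was lost in siWnt5A in 4 alternative settings, YIPF5 in siSRC1 in 5 and in siWnt5A in 1, and IRF7 in siSRC1 in 5 and in siWnt5A in 2, with the mean of its probes in both. Both comparisons rest on the same 3 siNT arrays, which alone makes calls and fold changes resemble each other. In 100 simulated sets of unchanged groups the median count of genes called in both in the same direction was 0, and 1 set had any, with 211 against the observed 267. The correlation of fold changes across genes, which are not independent replicates, was 0.37 against a simulated mean of 0.47, and 61.9% of genes had the same sign against 66.8%. The covariance was 0.0321 against a simulated mean of 0.013, a difference of 0.019. It was as large in 9 of the 100 sets. Since 3 control arrays cannot be split so that each part keeps 2, part of the excess may come from the shared controls. The count in the same direction was 129 without siNT replicate 2, 128 without siNT replicate 3, 171 without siWnt5A replicate 1 and 168 without siSRC1 replicate 2.

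**Figure D3:**
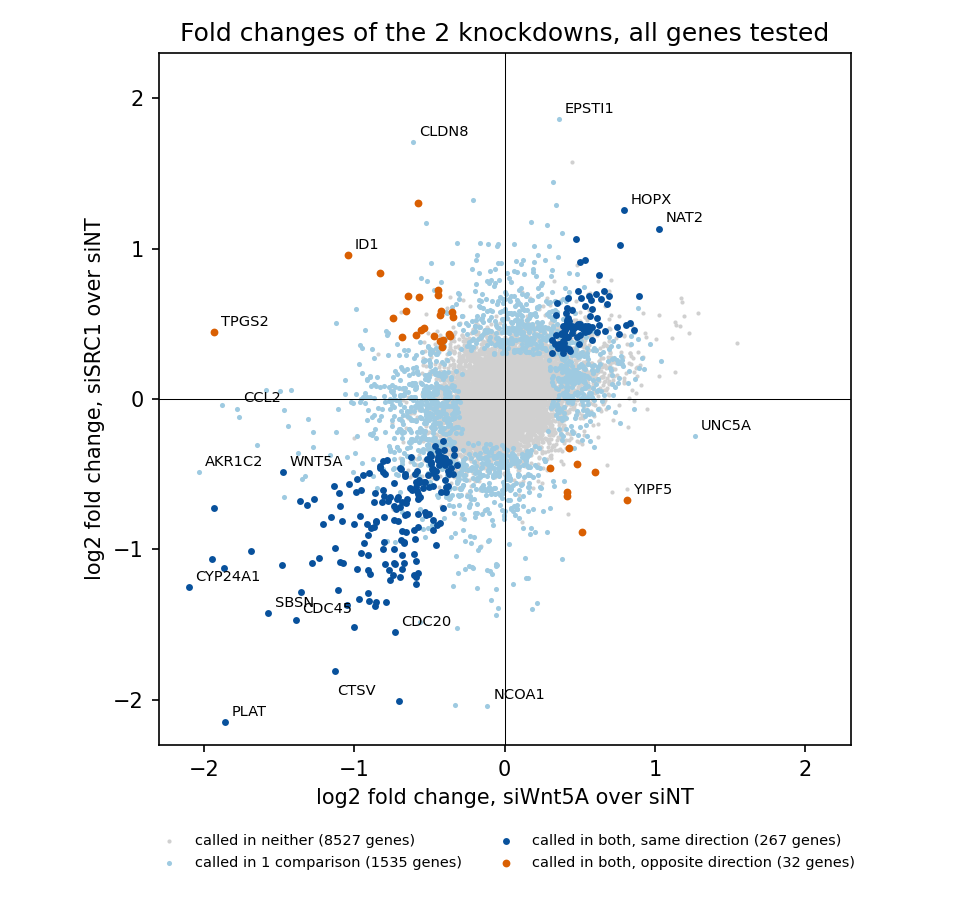
Log2 fold change against siNT of each of the 10361 genes tested, in siWnt5A (x axis) and siSRC1 (y axis); colours mark genes called in neither, in 1 or in both comparisons. The 267 genes called in both in the same direction outnumber the 32 called in opposite directions, and PLAT, CYP24A1 and CDC45 lie at the lower left.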

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

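The tests in this part were chosen before the results were seen.

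Of 3616 probes that passed the filter but have no single gene symbol here, and which enter none of the gene comparisons, 104 were higher in siWnt5A than in siNT and 110 lower by limma (214 called, 5.92% of them against 8.15% of the named probes). In siSRC1, 75 were higher and 97 lower (172 called, 4.76% against 7.92%). These probes were set apart because signal above the control level appears in data outside the main measurement. No explanation was tested.

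Other splits of the 6 arrays of each comparison were counted. The real split of siWnt5A and siNT called 1078 genes and the other splits at most 0; for siSRC1 and siNT the counts were 1055 and 0, and for siWnt5A and siSRC1 1820 and 0. In each comparison 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the other splits gave at most 1111, 860 and 816 genes, against 2869, 2556 and 3360. The other splits mix arrays of both groups, so differences between the groups add to their spread. Low counts there would follow from any such difference, whatever its source.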

How the results depend on the processing

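The covariate fit, and every setting for the lists that differ between the knockdowns and for the counts of M-phase, ATF4 and NF-kB genes, was chosen after seeing the data. No named gene reversed, while medians of some lists that did not pass changed sign. Of 107 comparisons of named genes 106 passed the threshold, and of 2324 values under alternatives 2169 kept their side and 155 no longer passed, most often EAF2 (18 settings), BEGAIN in siSRC1 (14) and OAS3 (13). Same-numbered arrays mostly did not deviate together: 1 of 7 pairs correlated above 0.1 (range -0.21 to 0.34), and no array correlated best with its own number. Pairing by number was thus not seen, but it cannot be excluded from 7 pairs, and siNT replicate 4 has no same-numbered partner. With the replicate number as a block, 458 genes were called in siWnt5A, 348 in siSRC1 and 104 in both in the same direction, and 5 ATF4 and unfolded protein response genes fell in siSRC1. That fit has fewer residual degrees of freedom. In it siNT replicate 4 is alone in its block and adds nothing to the comparisons with siNT, so the lower counts also reflect a lost control array. With the first component of the deviations within groups as a covariate, 1778 genes were called in siWnt5A. That component comes from the same arrays and is centred within each group. It leaves the fold changes as they are and takes up part of the spread, so the added calls follow from how it was made. With an estimated correlation camera called 2 lists in siWnt5A, 3 in siSRC1 and 0 between the knockdowns, where fry called 10, 7 and 9. All probes as separate rows gave 8 lists that differ, and trended robust moderation 7; the cause was not tested. Leaving out each array gave 441 to 999 genes in siWnt5A, 604 to 997 in siSRC1, 1099 to 1783 between them and 128 to 207 in both; 5 to 6, 4 to 6 and 4 to 7 lists; 20 to 29 and 24 to 30 M-phase genes; 9 to 14 ATF4 and 8 to 10 NF-kB genes; and log2 fold changes of -1.51 to -1.39 (WNT5A) and -2.11 to -1.97 (NCOA1). With median scaling 44.7% of calls in siWnt5A were higher, against 35.0%. A slide effect was not run, since the files name no slides. Signal over background limits dim genes: 65 of the calls in siWnt5A and 59 in siSRC1 have only a bound.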

Other observations

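The tests of a growth state of the siNT cultures, of siWnt5A material in the siSRC1 samples and of a batch marked by the replicate number were chosen only after the result was seen.

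The genes of this paragraph were chosen after their values were seen. Of 16 measured chemokine ligands 9 fell with siWnt5A, none rose and 7 were not called, while in siSRC1 3 fell, 2 rose and 11 were not called. In siWnt5A CXCL2 (log2 fold change -0.52, limma adjusted p = 0.0648) and CCL20 (-0.27, adjusted p = 0.123) were among those not called. CCL8 (-1.86), CX3CL1 (-1.68) and CXCL8 (-1.31) fell, and so did PTGS2, the inducible cyclooxygenase (-1.44). In siSRC1 CXCL8 was at -0.13 and PTGS2 at -0.18, neither called, and both differed between the knockdowns, where their list did not pass as a whole (camera adjusted p = 0.051; for the 2 genes limma adjusted p = 0.000873 and 0.000812). CCL2 (-1.71, adjusted p = 0.000173) and CXCL10 (-0.95, adjusted p = 0.000164) differed as well, while TNF fell in both (-1.24 and -1.05) and did not pass the test of a difference (adjusted p = 0.443).

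The genes of this paragraph, too, were chosen after their values were seen. Of the ATF4 and unfolded protein response list PSAT1 of serine synthesis (-0.77), the asparagine synthetase ASNS (-0.58) and CHAC1, which degrades glutathione (-0.71), fell in siSRC1. In siWnt5A they were at 0.00, 0.16 and 0.06, and each differed between the knockdowns (adjusted p = 0.000958, 0.000483 and 0.000947). Of the same list PHGDH (-0.16), MTHFD2 (-0.18) and SLC7A11 (-0.43) were not called in siSRC1 (adjusted p = 0.295, 0.304 and 0.0684). The chaperone HSPA5 rose in siWnt5A (0.76) and was at 0.14 in siSRC1 (difference 0.62, adjusted p = 0.0048). The Wnt receptor FZD6 fell in siSRC1, to 49.9% of siNT, and was at -0.18 in siWnt5A (difference 0.83, adjusted p = 0.00131). The adhesion molecule NCAM1 rose in siSRC1 (1.03), and the synaptic vesicle protein SYT1 fell in siWnt5A (-0.95).

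M-phase genes were lower in both knockdowns, on each of the 6 arrays. Chance spread of the 3 siNT arrays is argued against, since 0 of 100 simulated sets had both medians as low, and so are the correction and scaling of the arrays, since the highest median over 4 others was -0.33 and at least 92.9% of the called members stayed called. A different growth state of the siNT cultures could not be excluded. Between the knockdowns 8 of 34 M-phase genes differed, fewer than the 17 set as the bound. That comparison holds no siNT array, so no count in it could decide the question, and no untransfected culture is among the arrays. A fall of dividing cells after loss of each target is a hypothesis that stays open beside a different growth state, untested here.

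WNT5A was lower in the siSRC1 arrays, where it was not the target. Material from siWnt5A samples in the siSRC1 samples is argued against by the level of NCOA1. A share of 44.8% would be needed, which alone brings NCOA1 to 119, while it measured 70.4 ± 7.01. Of 59 other genes that fell at least 2-fold in siWnt5A, 24 lay in siSRC1 above the level that share would give. Among these were TPGS2 (mean log2 value 9.145 in siSRC1 and 8.70 in siNT) and SERPINB7 (10.38 and 10.42). The median log2 ratio of observed to that level over the 59 genes was -0.17. Genes that fell in both knockdowns, such as PLAT, can lie below that level without any mixing, so the set cannot decide the question. Chance in the siNT arrays stays open, because the smallest fall with a siNT array left out was -0.43 on the log2 scale and its adjusted p was 0.0579 (0.0308 to 0.0579 over the 3). A candidate explanation, that WNT5A depends in part on NCOA1, was not tested.

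Arrays of different groups deviated together from their group means: 1 component held 37.4% of the variance within groups, with siNT replicate 3 (-0.35), siWnt5A replicate 3 (-0.52) and siSRC1 replicate 1 (-0.46) on 1 side. It followed the brightness of the arrays, as the 95th percentile of signal relative to the group (r = -0.78, permutation p = 0.0185 over 216 permutations within groups; rho = -0.70, permutation p = 0.0509; r = -0.75 without the 2 farthest arrays; 9 arrays), which is consistent with a technical source such as the amount of labelled RNA, though the rank test missed 0.05. For dim probes near background, the 500 genes with the largest loadings lay at a median percentile of expression of 40.6 among the genes tested. The filter had already removed the probes detected on fewer than 3 arrays, so this value could not decide the question. A batch marked by the replicate number was not seen, since 1 of 7 same-numbered pairs correlated above 0.1, but 7 pairs cannot exclude it. Within siNT the 95th percentile hardly varied (1459, 1472 and 1463 in replicates 2, 3 and 4), while the component lay at -0.02, -0.35 and 0.37. The link with brightness thus rests mostly on the knockdown arrays, and the deviations of the siNT arrays are not accounted for by it. No biological explanation was tested. In 1 of the 100 simulated sets drawn with these deviations, unchanged arrays gave 1406 calls in a comparison, more than the 1078 of siWnt5A.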
